A study of Homo sapiens with 21 samples.

How the data were processed

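RNA was measured in 21 libraries that fall into 7 groups of 3. Total RNA was extracted with TRI reagent, made into stranded poly(A) libraries with a KAPA mRNA HyperPrep kit and sequenced in pairs of 50 nt reads, per the labels' protocols. The values are raw read counts per gene, deposited as whole numbers with 1 column per library and no pooling of replicates. The reads were aligned with STAR to GRCh38 (hg38) and counted with featureCounts, per the submitters' processing notes. The versions of these tools, the annotation release and the strand setting of the counting are not given in the sources used here, so reads from overlapping genes on opposite strands cannot be assumed to be separated. Genes with near-identical copies, such as SAA1 and SAA2, KRT8, KRT18, HSPA8, HSPD1 and the mitochondrially encoded transcripts, can share reads with those copies, and their levels are uncertain to that extent.

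The deposited table holds 60617 Ensembl gene identifiers. Of these, 60357 were paired with a symbol from a table of gene names, 237 more took their name from GENCODE v29, and 58444 are in GENCODE v29, from which the GRCh38 coordinates come. XIST, TSIX and Y-linked genes, 511 identifiers in all, were left out of every test and list. Total counts per library ran from 22998450 to 46501043.

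Libraries were grouped by their titles. The tests, the gene lists, the named-gene rule and most alternatives were fixed before the data were examined. Comparisons among stem-cell-derived adipocytes came from 1 fit of their 18 libraries with a coefficient per group. Each comparison with primary adipocytes was fitted on its own 6 libraries, because primary cells can vary more than libraries of a cell line. Genes with low counts were removed with filterByExpr (minimum count 10, minimum total count 15), libraries were scaled by TMM, and the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3 was applied. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. The fit of 18 libraries tested 18519 genes, and the fits with primary adipocytes tested 16333, 17147 and 17072 genes for the Published, Sensitized and Hyper cultures. A log2 fold change is given with its standard error, and a level as CPM, the scaled count per library that edgeR gives, with the SD over libraries. CPM of a group differ slightly between fits, because the scaling is computed within each fit.

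Gene lists, 34 in all, were drawn up from textbook knowledge: metabolic pathways, genes that insulin regulates, stress and hormone responses, adipocyte and progenitor markers, markers of other cell types that the preparations could hold, and signs of RNA quality. Lists with at least 3 tested members were tested with camera of limma 3.58.1 (preset correlation 0.01), again with an estimated correlation, and with fry. Adjustment was over the lists within a comparison, and members were counted both over all genes tested and adjusted over the list alone.

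Named genes followed a rule. For each comparison the 6 largest rises and 6 largest falls were taken (5 of each for differences of responses) among called genes with a mean of at least 10 CPM and, between 2 groups, no overlap of libraries. A fixed panel of insulin-regulated or adipocyte genes was added whatever its values, and the 2 members of smallest adjusted p in each list that camera called. Genes without a symbol, long intergenic and antisense RNAs, pseudogenes, HLA, immunoglobulin and T cell receptor genes and genes commonly deleted in people were not named. A few genes that the rule selects are not reported here. Any other gene that is named was chosen after its values were seen, and is said to be.

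The log2 CPM (prior count 2) of each culture were also compared with the mean of the primary libraries by Spearman correlation across genes, with an exact two-sided permutation test between groups. Alternatives were RLE size factors, no low-count filter, a minimum change of 2-fold, DESeq2 1.42.0, fits of the compared libraries alone, a fit of all libraries without acute insulin for the comparisons with primary adipocytes, the replicate number as a block, and each library left out in turn. Chosen after seeing the data were a correction for GC content, the omission of the Published-protocol libraries, the omission of Published replicate 1 from results that do not compare the Published culture, and combinations of these omissions with the correction. The GC correction used a smooth trend (window of 0.3 of the genes) of each library's log2 CPM against transcript GC content as an offset, and 98.8% of the tested genes had a GC value. The GC trend of a library is the median log2 deviation from the mean over libraries in the fifth of genes above 56.1% GC minus that in the fifth under 40.2%.

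The fits named here and the list test were tried on simulated counts drawn from the means, dispersions and sizes of the real libraries. Each gene had 1 dispersion for all libraries of a fit, so groups of unequal spread were not simulated. The recovery in the real data can therefore differ. For the insulin response of the Sensitized culture, edgeR recovered 77% of 100 genes changed 1.5-fold and 95% of 100 changed 2-fold, and called 7 unchanged genes. DESeq2 recovered 80% and 95%, and called 25 unchanged genes. With a simulated GC trend left in, edgeR recovered 70% and 94%, and called 11 unchanged genes. With GC correction of that trend it recovered 76% and 95%, and called 16. For the difference between the Sensitized and Published responses edgeR recovered 62% and 78%, and for that between Hyper and Sensitized 49% and 83%. In the comparison of Sensitized with Published cultures it recovered 83% and 96%. With primary adipocytes, 2-fold and 8-fold changes were recovered in 29% and 96% of genes for Published, 22% and 98% for Sensitized, and 36% and 94% for Hyper. In the list test on simulated data, the moved list was called and 0 of 20 unchanged lists were. Simulated genes were drawn independently of each other, so false list calls from correlated genes could not appear there.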

Results

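Poly(A) RNA was sequenced from 21 libraries to describe a model of insulin resistance in fat cells grown from stem cells. Of the 7 groups of 3 libraries, 1 was primary human adipocytes from adipose tissue (Primary). The other 6 were adipocytes differentiated from Hues9, an established line of human embryonic stem cells. These had followed the original differentiation protocol (Published), or had then spent 5 days in low-glucose DMEM with 100 pM insulin (Sensitized) or with 3 nM insulin (Hyper). Each culture was collected without and with 10 nM insulin for 4 hours, here called acute insulin. Nothing in the labels says that replicates were separate cultures or donors, so p-values measure the spread between these samples, which may be technical. All 21 pairs of replicates differed by more than sampling noise, with a chi-square per degree of freedom of 3.25 to 260.

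The gene with the most counts was SCD, the stearoyl-CoA desaturase of fat synthesis, in Primary, and COL1A1, a chain of type I collagen, in each stem-cell-derived group. The first principal component, 64.2% of the variance, parted primary adipocytes from all stem-cell-derived ones. The second, 13.3%, parted Published libraries from Sensitized and Hyper libraries.

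**Figure D1:**
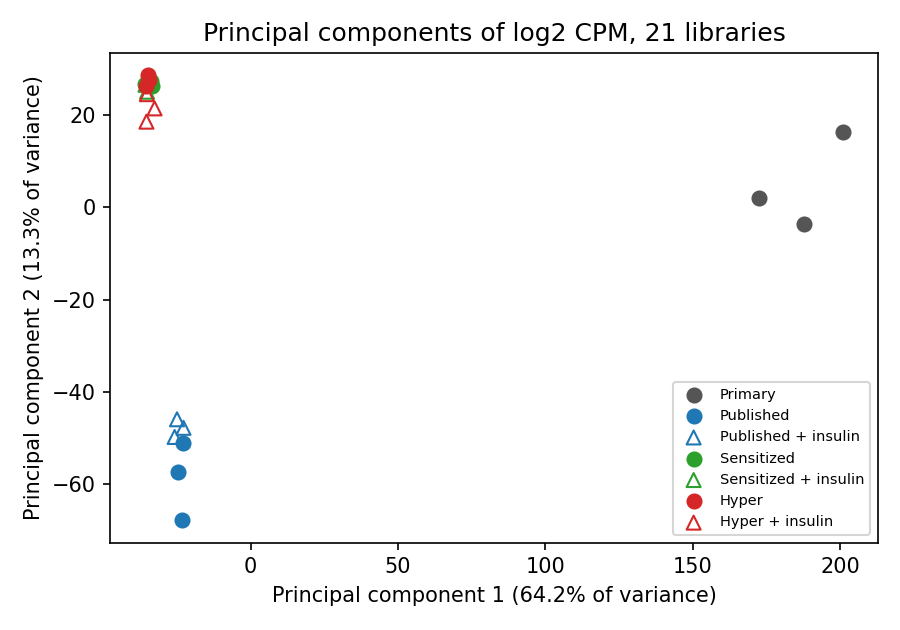
Principal components of log2 CPM in 21 libraries, 1 point per library, with the share of variance on each axis (64.2% and 13.3%). Primary adipocytes lie far right of all stem-cell-derived libraries, and the Published libraries lie apart from Sensitized and Hyper libraries on the second axis.

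Some Published libraries differed from the rest in 2 technical measures. Mitochondrially encoded transcripts took 19.03%, 11.98% and 8.55% of the counts in the 3 Published libraries without acute insulin, a mean of 13.2% ± 5.35 (SD, n = 3). The mean was 9.07% ± 0.639 with acute insulin, 7.83% ± 0.140 in Sensitized, 8.11% ± 0.109 in Hyper and 8.75% ± 0.214 in Hyper with acute insulin. In Primary it was 8.32% ± 4.39. The GC trend, the log2 level of GC-rich relative to GC-poor genes, was −0.69, −0.31 and −0.09 in the same 3 Published libraries and −0.05, −0.31 and −0.08 with acute insulin, so that Published replicate 3 lay within the range of the other libraries in both measures. It was 0.14 to 0.22 in Sensitized, 0.16 to 0.29 in Hyper and −0.11 to 0.08 in Hyper with acute insulin.

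**Figure D2:**
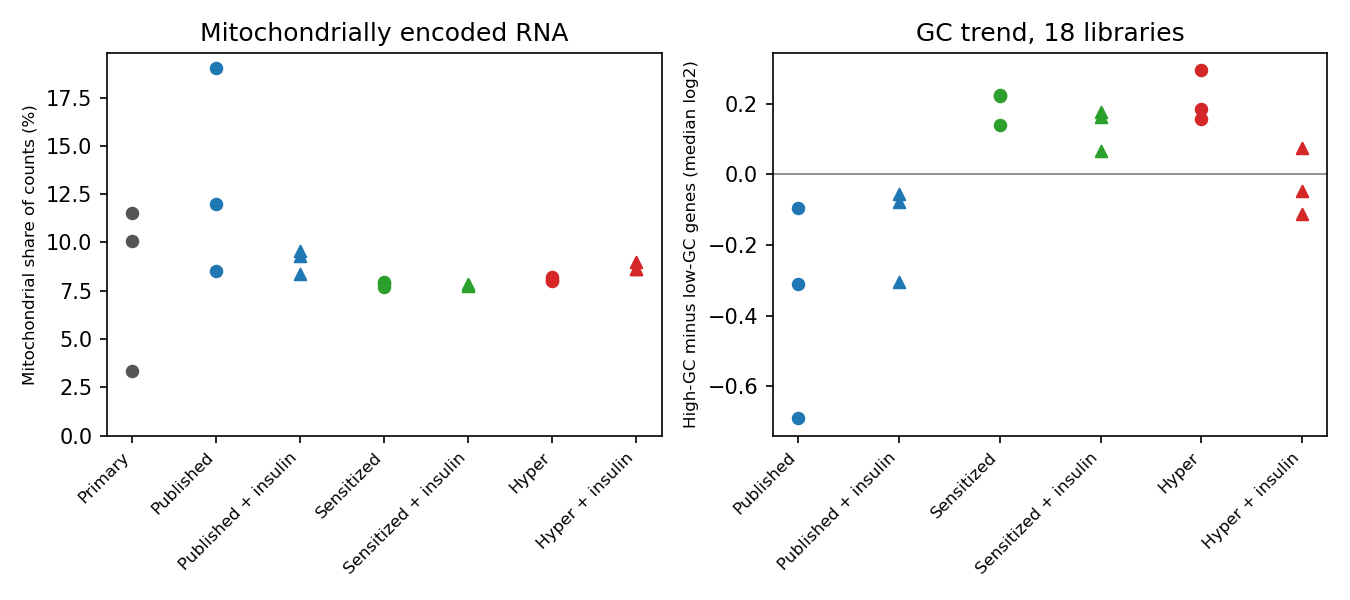
Share of counts from mitochondrially encoded transcripts (percent) in 21 libraries and the GC trend (log2, GC-rich minus GC-poor genes) in the 18 stem-cell-derived libraries, 1 point per library, with triangles for acute insulin. The highest mitochondrial share, 19.03%, and the lowest GC trend, −0.69, belong to Published replicate 1.

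The first culture comparison asks how 5 days in low-glucose medium with 100 pM insulin changed the cells (Sensitized minus Published, both without acute insulin). Glucocorticoid-response genes were lower. FKBP5, a co-chaperone of the glucocorticoid receptor, fell from 540 ± 58.0 to 52.8 ± 3.57 CPM (SD, n = 3; log2 −3.35 ± 0.08, SE), and the transcription factor KLF9 fell from 99.6 ± 2.11 to 12.8 ± 0.893 CPM. Of 17 members tested, 15 fell, 1 rose and 1 did not pass, as also adjusted over the list alone, with adjusted p = 2.87e-07 with an estimated correlation. Inflammatory genes fell too: SAA1, an acute-phase protein, from 112 ± 3.40 to 2.50 ± 0.126 CPM, its neighbour SAA2 (log2 −5.90 ± 0.21) and the interleukin-1 receptor IL1R1 (−2.28 ± 0.07). In that list 18 of 25 fell and 3 rose, the same adjusted over the list alone (adjusted p = 0.00469 with an estimated correlation). Thermogenic genes were among the largest falls. UCP1, the uncoupling protein of brown fat, went from 174 ± 3.59 to 14.1 ± 1.51 CPM, and DIO2, which activates thyroid hormone, from 906 ± 117 to 73.3 ± 3.15 CPM. The brown and beige list as a whole did not pass (6 of 16 rose, 3 fell, camera adjusted p = 0.0855).

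Genes of the amino acid response driven by ATF4 rose as a group. In this list 26 of 28 rose and 2 fell, also adjusted over the list alone, with a median log2 change of 1.00 (adjusted p = 0.0268 with an estimated correlation). Its leading members were the cystine transporter SLC7A11, which rose from 55.3 ± 2.22 to 156 ± 2.76 CPM, and PSAT1 of serine synthesis, at 1.59 ± 0.07. Hypoxia-response genes rose, 18 of 22 against 3 that fell (18 and 4 adjusted over the list alone; adjusted p = 0.00512 with an estimated correlation). They included the growth factor VEGFA, up 1.28 ± 0.06, and the glucose transporter SLC2A1, up 1.95 ± 0.10. Insulin signalling genes rose in 16 of 29 cases and fell in 5, also adjusted over the list alone (adjusted p = 0.0306 with an estimated correlation). The insulin receptor INSR rose by 0.37 ± 0.06, its substrates IRS1 by 0.41 ± 0.06 and IRS2 by 0.54 ± 0.08, and the insulin-responsive glucose transporter SLC2A4 by 0.81 ± 0.11. Adipose progenitor markers fell in 11 of 21 cases and rose in 6, also adjusted over the list alone (adjusted p = 0.0341 with an estimated correlation), led by the leptin receptor LEPR at −1.22 ± 0.06 and the matrix protein POSTN at −1.13 ± 0.07. Mesothelial markers rose in 4 of 8 cases (5 adjusted over the list alone) and fell in 1 (adjusted p = 0.0306 with an estimated correlation). The members that rose most clearly were the calcium-binding CALB2, at 1.71 ± 0.07, and the keratin KRT18, at 2.35 ± 0.11, which other epithelia also express.

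Adipocyte markers moved both ways. The fat-cell regulators PPARG and CEBPA rose by 0.85 ± 0.05 and 1.35 ± 0.13, the lipid droplet coat PLIN1 by 0.85 ± 0.07, the lipase LPL by 0.55 ± 0.06 and fatty acid synthase FASN by 0.74 ± 0.17. The hormone ADIPOQ fell from 1422 ± 132 to 755 ± 44.7 CPM, the lipid carrier FABP4 by 1.62 ± 0.11, the hormone-sensitive lipase LIPE by 0.43 ± 0.12 and the gluconeogenic PCK1 by 1.65 ± 0.11. The mean level of LEP was under 1 CPM in both cultures. Of 24 mature adipocyte markers 14 rose and 6 fell (15 and 6 adjusted over the list alone; adjusted p = 0.409 with an estimated correlation). The largest rises of all were FABP7, a fatty acid carrier, from 5.48 ± 1.31 to 111 ± 11.6 CPM, the cholesterol exporter ABCG1 at 3.38 ± 0.09, the secreted ANGPTL7 at 3.36 ± 0.10, CLCA2 at 3.34 ± 0.15, the keratin KRT16 at 3.13 ± 0.16 and the iron carrier TF at 3.06 ± 0.10. The protease CORIN fell by 4.59 ± 0.10. The integrin ITGA8 was at −3.42 ± 0.11.

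Other lists were called by camera at its preset correlation but not with an estimated one. Of 25 interferon-response genes 22 fell and 0 rose, also adjusted over the list alone (adjusted p = 0.0811 with an estimated correlation), among them the RNA sensor IFIH1 at −1.58 ± 0.10 and IFI44 at −1.20 ± 0.08. Cholesterol synthesis genes fell in 15 of 25 cases and rose in 7, also adjusted over the list alone (adjusted p = 0.0827 with an estimated correlation). MSMO1 was at −0.96 ± 0.04 and SQLE at −1.12 ± 0.05. Of 40 nuclear genes of oxidative phosphorylation 25 fell, such as SDHD at −0.62 ± 0.05 and ATP5F1C at −0.72 ± 0.06, and 4 rose (26 and 6 adjusted over the list alone; adjusted p = 0.265 with an estimated correlation). Of 27 matrix genes 14 fell, such as COL3A1 at −0.85 ± 0.06 and COL5A2 at −0.70 ± 0.05, and 3 rose (14 and 4 adjusted over the list alone; adjusted p = 0.265 with an estimated correlation). Glycolysis genes rose in 13 of 19 cases, while hexokinase HK2 fell by 1.58 ± 0.06 as 1 of 2 falls (14 and 2 adjusted over the list alone; adjusted p = 0.450 with an estimated correlation). Immediate early genes rose in 18 of 28 cases, such as ETV5 at 0.94 ± 0.08, and fell in 3 (the same adjusted over the list alone; adjusted p = 0.168 with an estimated correlation). Among the latter, DUSP1 fell from 33.5 ± 2.12 to 16.7 ± 0.782 CPM. Of 21 genes of the unfolded protein response 7 rose, such as HYOU1 at 0.85 ± 0.05 and SEL1L at 0.76 ± 0.05, and 3 fell, also adjusted over the list alone (adjusted p = 0.232 with an estimated correlation).

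FOXO targets that insulin lowers rose in 7 of 24 cases and fell in 8, also adjusted over the list alone (adjusted p = 0.245 with an estimated correlation). Their median was 0.00 while their mean was −0.33 and the test pointed down. The pyruvate dehydrogenase kinase PDK4 fell by 2.24 ± 0.09 and the muscle-wasting ligase FBXO32 by 1.46 ± 0.07. Mural and smooth muscle markers fell in 9 of 14 cases, such as LMOD1 at −1.65 ± 0.09, and rose in 3, such as NOTCH3 at 1.60 ± 0.10 (the same adjusted over the list alone; adjusted p = 0.270 with an estimated correlation). Neural markers rose in 8 of 13 cases, such as NEFL at 1.97 ± 0.18 and MAP2 at 0.68 ± 0.08, and fell in 1, also adjusted over the list alone (adjusted p = 0.0713 with an estimated correlation). Cartilage and bone markers fell in 6 of 13 cases, such as ALPL at −1.17 ± 0.06 and COL11A1 at −1.54 ± 0.08, and rose in 4 (6 and 5 adjusted over the list alone; adjusted p = 0.118 with an estimated correlation). All 13 mitochondrially encoded transcripts fell, also adjusted over the list alone, such as MT-CO3 at −1.12 ± 0.16 and MT-CO1 at −0.98 ± 0.16 (adjusted p = 0.409 with an estimated correlation).

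Of 18519 genes tested, edgeR called 9288, of which 4777 rose and 4511 fell, and 1988 changed at least 2-fold. The Published libraries had the higher mitochondrial share and the lower GC trend, and the called rises had a median GC content of 54.2% against 43.1% for the falls. With a correction for GC content 8464 genes were called, 6843 of them among the 9288, and the mature adipocyte list lost its call (adjusted p = 0.0931).

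**Figure D3:**
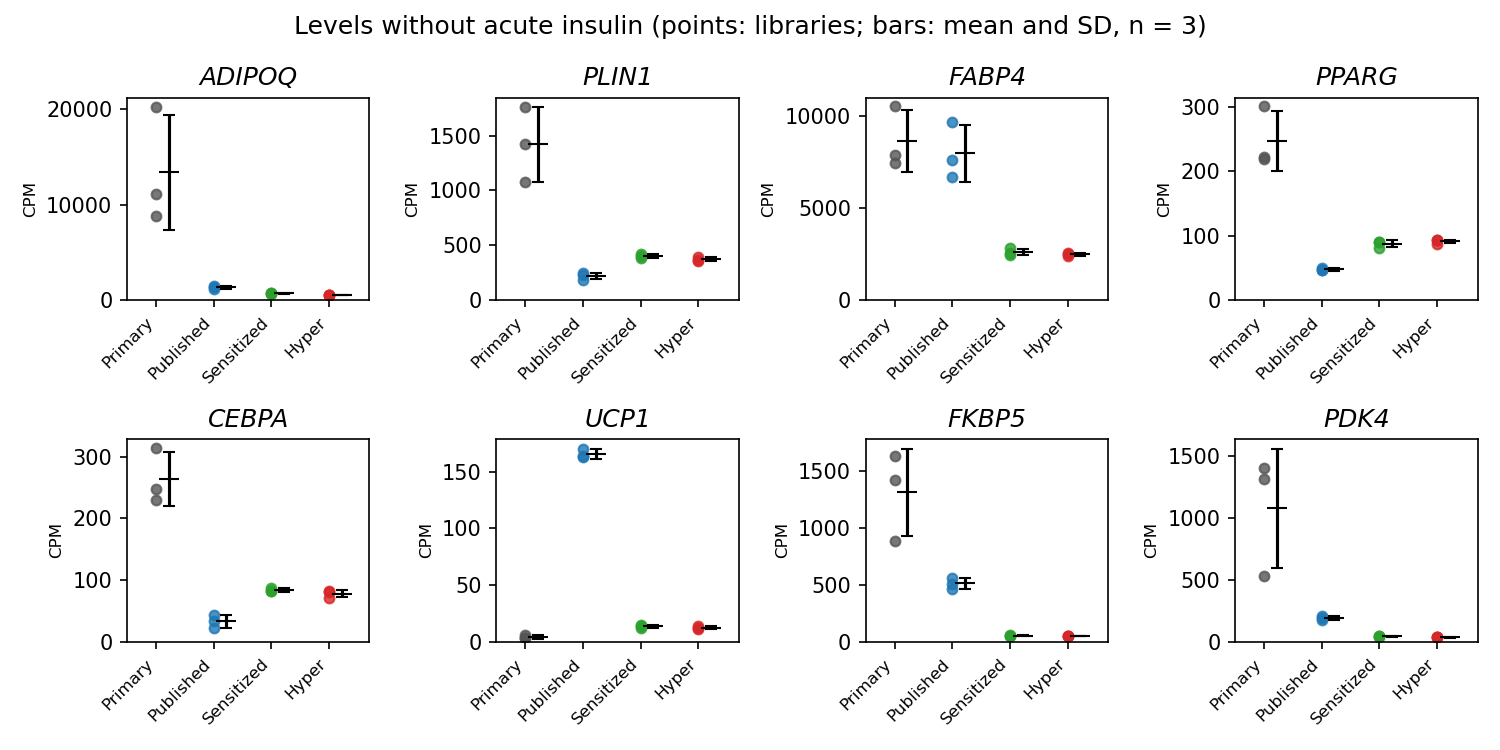
Levels (CPM) of ADIPOQ, PLIN1, FABP4, PPARG, CEBPA, UCP1, FKBP5 and PDK4 in Primary, Published, Sensitized and Hyper without acute insulin, with points for libraries and bars for the mean and SD (n = 3). ADIPOQ was 13401 CPM in Primary and 584 in Hyper, and FKBP5 was 512 CPM in Published and 50.7 in Sensitized.

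Raising the insulin of the 5-day culture from 100 pM to 3 nM asks what chronic high insulin does (Hyper minus Sensitized, both without acute insulin). In 18519 genes edgeR called 3. ANGPTL7, a secreted angiopoietin-like protein, rose from 37.2 ± 3.73 to 52.2 ± 1.74 CPM (SD, n = 3; log2 0.49 ± 0.08, SE; adjusted p = 0.0219). GPX3, a secreted glutathione peroxidase, fell from 139 ± 3.23 to 109 ± 2.79 CPM (−0.35 ± 0.05; adjusted p = 0.0153). The remaining gene, TDO2, a tryptophan-degrading enzyme whose level lay under the minimum for named genes, was chosen after its values were seen and rose from 4.82 to 8.43 CPM (0.81 ± 0.11; adjusted p = 0.00738). None of the adipocyte panel passed: ADIPOQ was at −0.31 ± 0.08 (adjusted p = 0.796), PPARG at 0.06 ± 0.05, PLIN1 at −0.11 ± 0.07, INSR at −0.13 ± 0.06 and IRS2 at −0.12 ± 0.08. In this edgeR test 559 genes had an unadjusted p under 0.05 against 926 expected by chance, so it was conservative here. A gene that did not pass is therefore not shown to be unchanged.

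Lists called by camera had 0 members called in this comparison, and none kept its call with an estimated correlation. The mature adipocyte list had a median of −0.11 (0 up and 3 down of 24 adjusted over the list alone; adjusted p = 0.236 with an estimated correlation), with CIDEA, a lipid droplet protein, at −0.51 ± 0.12. The lipid droplet list of 21 was at −0.07 (0 up and 2 down adjusted over the list alone; adjusted p = 0.471 with an estimated correlation). The brown and beige list of 16 was at −0.05 (0 up and 1 down adjusted over the list alone; adjusted p = 0.170 with an estimated correlation). FOXO targets were at −0.06 (0 and 0 adjusted over the list alone; adjusted p = 0.236 with an estimated correlation). On the side above 0 were cholesterol synthesis at 0.09 (3 up and 1 down of 25 adjusted over the list alone; adjusted p = 0.170 with an estimated correlation). Fatty acid synthesis was at 0.06 (2 up of 23 adjusted over the list alone; adjusted p = 0.628 with an estimated correlation). Glycolysis was at 0.10 (0 up and 1 down of 19 adjusted over the list alone; adjusted p = 0.628 with an estimated correlation). Oxidative phosphorylation was at 0.05 (0 of 40 adjusted over the list alone; adjusted p = 0.605 with an estimated correlation). Macrophage markers were at 0.31 (0 of 12 adjusted over the list alone; adjusted p = 0.170 with an estimated correlation). The 3 genes were also called by DESeq2 among its 9, and without the Published libraries among 19. Leaving out Sensitized replicate 1 or 2 or Hyper replicate 3 gave 0 calls, leaving out Hyper replicate 1 or 2 gave 1, and leaving out Published replicate 1 gave 6.

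Acute insulin in the Sensitized culture raised cholesterol synthesis genes and lowered FOXO targets. MSMO1, a sterol oxidase of cholesterol synthesis, rose from 133 ± 4.10 to 176 ± 1.96 CPM (SD, n = 3; log2 0.41 ± 0.04, SE; adjusted p = 1.28e-05). Of 25 members 6 rose and 0 fell (11 and 1 adjusted over the list alone; adjusted p = 0.00236 with an estimated correlation). PDK4, which holds back glucose oxidation, fell from 42.9 ± 2.70 to 20.1 ± 1.49 CPM (log2 −1.10 ± 0.10; adjusted p = 2.63e-06), PIK3IP1, a brake on PI3 kinase, from 17.2 ± 0.453 to 10.1 ± 0.518 CPM, and KLHL24 from 66.5 ± 0.667 to 40.6 ± 1.56 CPM. Of 24 FOXO targets 4 fell and 0 rose (9 and 1 adjusted over the list alone; adjusted p = 0.00157 with an estimated correlation).

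Heat shock genes rose in 2 of 18 cases and fell in 0 (3 and 0 adjusted over the list alone; adjusted p = 0.0237 with an estimated correlation): the chaperones HSPH1 by 0.37 ± 0.05 and HSPA8 by 0.36 ± 0.07. The glucocorticoid list was lower (adjusted p = 0.0155 with an estimated correlation), with PDK4 its 1 called member of 17, and 2 that fell adjusted over the list alone. Among the largest rises were SPRY4, a feedback inhibitor of receptor tyrosine kinases, from 10.7 ± 0.771 to 18.4 ± 1.27 CPM, UCP1 from 14.1 ± 1.51 to 22.7 ± 1.17 CPM, LBHD1 at 0.75 ± 0.12, the kinesin KIF21A at 0.65 ± 0.10 and ARHGAP20 at 0.60 ± 0.06. COQ8A of coenzyme Q synthesis fell by 0.57 ± 0.07 and MOCS1 by 0.50 ± 0.07. Of the panel, INSR was at −0.24 ± 0.06 (adjusted p = 0.0617), IRS2 at −0.31 ± 0.08 (0.0791) and INSIG1 at 0.20 ± 0.05 (0.114), none past the threshold. SREBF1 was at −0.28 ± 0.10 and FASN at −0.32 ± 0.17, also not past it, and the fatty acid synthesis list of 23 had 0 called members (camera adjusted p = 0.104). With GC correction INSR at −0.24 (adjusted p = 0.0253), IRS2 at −0.28 (0.0396) and SREBF1 at −0.21 (0.0237) passed.

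Other lists were called at the preset correlation only. Immediate early genes rose in 3 of 28 cases (3 up and 1 down adjusted over the list alone; adjusted p = 0.358 with an estimated correlation): SPRY4, and DUSP4, a phosphatase of MAP kinases, which rose from 5.98 ± 0.490 to 13.6 ± 0.402 CPM, were the clearest. Ribosome biogenesis genes had a median of 0.09 (2 of 30 up adjusted over the list alone; adjusted p = 0.0948 with an estimated correlation). NOP16 was at 0.40 ± 0.10 and NOP56 at 0.20 ± 0.05, neither called, and NOP56 passed with GC correction. The interferon list of 25 was at 0.20 (0 called, 0 adjusted over the list alone; adjusted p = 0.358 with an estimated correlation). The proliferation list of 29 was at −0.21 (0 and 0 adjusted over the list alone; adjusted p = 0.358 with an estimated correlation). Mature adipocyte markers were at −0.10 (0 called of 24, 2 up and 4 down adjusted over the list alone; adjusted p = 0.358 with an estimated correlation). Oxidative phosphorylation was at −0.07 (0 of 40 adjusted over the list alone; adjusted p = 0.501 with an estimated correlation). Fatty acid oxidation was at −0.05, with PDK4 alone called of 25 and adjusted over the list alone (adjusted p = 0.358 with an estimated correlation). Of 18519 genes edgeR called 74, of which 43 rose and 31 fell, and DESeq2 called 199 that held 72 of them. Without the Published libraries 404 genes were called, all 74 among them. Leaving out Sensitized replicate 1, 2 or 3 gave 36, 31 and 47 calls, leaving out replicate 1 or 3 with acute insulin 35 and 38, and leaving out Published replicate 1 gave 211.

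Most of the genes called for acute insulin in the Hyper culture fell. JUNB, a subunit of AP-1, fell from 17.1 ± 0.416 to 7.42 ± 0.844 CPM (SD, n = 3; log2 −1.20 ± 0.25, SE; adjusted p = 0.0335). PPDPF fell by 1.11 ± 0.20, the adipokine CFD (adipsin) by 1.02 ± 0.21, the lipoprotein APOE from 1107 ± 66.3 to 570 ± 90.3 CPM, DVL1 of Wnt signalling by 0.81 ± 0.19 and PLEKHF1 by 0.79 ± 0.16. UCP1 rose from 12.9 ± 1.62 to 24.2 ± 6.11 CPM (log2 0.90 ± 0.13), the fatty acid carrier FABP3 by 0.45 ± 0.09, the anion channel subunit LRRC8B by 0.40 ± 0.07 and IFIT5 by 0.29 ± 0.06. IDI1, an isomerase of cholesterol synthesis, rose from 234 ± 16.7 to 281 ± 13.7 CPM (0.26 ± 0.06; adjusted p = 0.0441).

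FOXO targets fell in 2 of 24 cases and rose in 0 (8 and 1 adjusted over the list alone; adjusted p = 0.0983 with an estimated correlation): IRS2 by 0.40 ± 0.08 and KLHL24 by 0.35 ± 0.06. PDK4 was at −0.31 ± 0.09 (adjusted p = 0.132), PIK3IP1 at −0.40 ± 0.12 (0.105), SREBF1 at −0.40 ± 0.10 (0.0572) and INSR at −0.16 ± 0.06 (0.205), none past the threshold. Ribosome biogenesis genes had a median of 0.10 (0 called of 30, 2 up adjusted over the list alone; adjusted p = 0.365 with an estimated correlation). The heat shock list of 18 tested higher at 0.14 (6 up and 1 down adjusted over the list alone; adjusted p = 0.365 with an estimated correlation), while its 1 called member, the small chaperone HSPB1, fell by 0.37 ± 0.08. The interferon list was at 0.28 (0 called of 25, 12 up and 2 down adjusted over the list alone; adjusted p = 0.496 with an estimated correlation). Fatty acid oxidation was at 0.09 (0 of 25 adjusted over the list alone; adjusted p = 0.496 with an estimated correlation). Mural markers were at −0.14 (0 of 14 adjusted over the list alone; adjusted p = 0.365 with an estimated correlation).

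Of 18519 genes edgeR called 111 in the Hyper response, of which 7 rose and 104 fell, and DESeq2 called 409, among them 109 of these. The libraries with acute insulin had the lower GC trend, and the 104 falls had a median GC content of 64.3% against 47.8% for all genes. With GC correction 37 genes were called, 24 of them among the 111, with 8 rises and 29 falls. Of the genes named above, LRRC8B went to 0.34 and IDI1 to 0.21 (adjusted p = 0.0561 each), IFIT5 to 0.23 (0.134), DVL1 to −0.36 (0.0526), IRS2 to −0.28 (0.0821), CFD to −0.65 (0.286), PLEKHF1 to −0.36 (0.294) and HSPB1 to −0.03 (0.951), and lost the call, while PDK4 gained it at −0.37 (0.0417). Without the Published libraries 1644 genes were called, 553 up and 1091 down, and with GC correction in addition 593, 266 up and 327 down. Leaving out Hyper replicate 1, 2 or 3 gave 4, 0 and 0 calls, leaving out replicate 1, 2 or 3 with acute insulin 107, 2 and 2, and leaving out Published replicate 1 gave 841.

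In the Published culture, edgeR called 0 genes in response to acute insulin, with 2860 of 18519 at an unadjusted p under 0.05, and DESeq2 called 31. Of genes called in Sensitized, MSMO1 was at a log2 change of 0.02 ± 0.04 (SE, n = 3; adjusted p = 0.857), PDK4 at 0.00 ± 0.09 around a level of 202 ± 20.9 CPM (SD), KLHL24 at 0.04 ± 0.06, and PIK3IP1 at 0.28 ± 0.12 (adjusted p = 0.263). Mitochondrially encoded transcripts tested lower, with a median of −0.82 and MT-ND1 at −0.90 ± 0.23 (0 called of 13, all 13 down adjusted over the list alone; adjusted p = 0.816 with an estimated correlation), and the mitochondrial share was 13.2% without and 9.07% with insulin. Immediate early genes tested higher at 0.14, with JUNB at 0.83 ± 0.24 and IER2 at 0.62 ± 0.17 (0 called of 28, 2 up adjusted over the list alone; adjusted p = 0.816 with an estimated correlation). Skeletal muscle markers tested lower at −0.66, with CHRNA1 at −0.66 ± 0.23 and MYL4 at −0.78 ± 0.34 (0 called of 13, 0 adjusted over the list alone; adjusted p = 0.816 with an estimated correlation). Leaving out Published replicate 3 gave 2972 calls, leaving out Published replicate 2 or Published replicate 1 with insulin gave 1 call each, and the muscle list turned to a median of 0.07 without Published replicate 2.

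**Figure D4:**
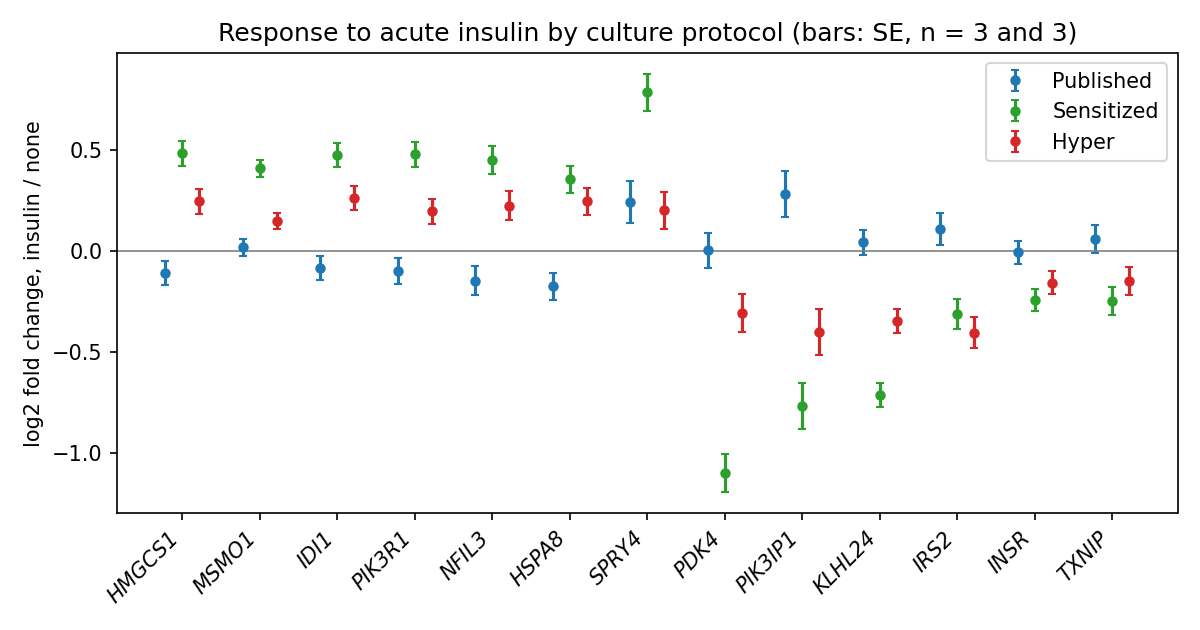
Log2 fold changes to acute insulin with their SE (n = 3 libraries per group) in Published, Sensitized and Hyper cultures for HMGCS1, MSMO1, IDI1, PIK3R1, NFIL3, HSPA8, SPRY4, PDK4, PIK3IP1, KLHL24, IRS2, INSR and TXNIP. PDK4 was at 0.00 in Published, −1.10 in Sensitized and −0.31 in Hyper, and MSMO1 at 0.02, 0.41 and 0.15.

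Whether the Sensitized culture answered insulin differently from the Published one was tested as the difference of both responses. The difference was above 0 for cholesterol synthesis genes, with HMGCS1 at 0.59 ± 0.08 (SE, n = 3 libraries per group; adjusted p = 0.00300) and MSMO1 at 0.39 ± 0.06. In that list 4 of 25 passed above 0 and 0 below (8 and 0 adjusted over the list alone; adjusted p = 0.153 with an estimated correlation). It was below 0 for the FOXO targets PDK4, at −1.10 ± 0.13 (adjusted p = 0.000366), PIK3IP1, at −1.05 ± 0.16, and KLHL24, at −0.76 ± 0.09. Of 24 targets 3 passed below 0 and 0 above (7 and 0 adjusted over the list alone; adjusted p = 0.0393 with an estimated correlation). PIK3R1, a regulatory subunit of PI3 kinase, was at 0.58 ± 0.09, the transcription factor NFIL3 at 0.60 ± 0.10, the synaptic vesicle protein SYN2 at 0.96 ± 0.17, LRRC8B at 0.57 ± 0.11, COQ8A at −0.72 ± 0.10 and the repressor HBP1 at −0.51 ± 0.09.

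The heat shock list had 2 of 18 members past the test above 0 and 0 below (7 and 0 adjusted over the list alone; adjusted p = 0.112 with an estimated correlation), HSPA8 at 0.53 ± 0.09 and HSPH1 at 0.39 ± 0.07. Ribosome biogenesis had a median difference of 0.16 (0 called of 30, 4 up adjusted over the list alone; adjusted p = 0.170 with an estimated correlation). Mature adipocyte markers were at −0.16 (0 called of 24, 4 down adjusted over the list alone; adjusted p = 0.614 with an estimated correlation). The lipid droplet list was at −0.17 (0 called of 21, 3 down adjusted over the list alone; adjusted p = 0.623 with an estimated correlation). The glucocorticoid list was at −0.08, with PDK4 its 1 called member of 17 (2 down adjusted over the list alone; adjusted p = 0.112 with an estimated correlation). Oxidative phosphorylation was at −0.11 (0 of 40 adjusted over the list alone; adjusted p = 0.631 with an estimated correlation). Proliferation was at −0.27 (0 called of 29, 1 down adjusted over the list alone; adjusted p = 0.607 with an estimated correlation). Interferon was at 0.19 (0 of 25 adjusted over the list alone; adjusted p = 0.822 with an estimated correlation). Mitochondrially encoded transcripts, whose share was highest in Published without insulin, were at 0.80 (0 called of 13, 11 up adjusted over the list alone; adjusted p = 0.607 with an estimated correlation). Of 18519 genes edgeR called 27, 18 above 0 and 9 below, DESeq2 called 157 with all 27 among them, and the fit of the 12 libraries concerned called 14, without NFIL3, LRRC8B, SYN2, HSPA8 and HSPH1. Leaving out Published replicate 3 gave 2038 calls, Published replicate 1 gave 42, Sensitized replicate 2 gave 17 and Sensitized replicate 3 with insulin gave 12, and with GC correction 65 genes were called, without MSMO1, which went from 0.39 to 0.31 (adjusted p = 0.0539).

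The difference between the Hyper and Sensitized responses passed for no gene in edgeR, with 959 of 18519 genes at an unadjusted p under 0.05 against 926 expected by chance, and DESeq2 called 2, PDK4 and MSMO1. With GC correction PDK4 was the 1 gene called, at 0.74 (adjusted p = 0.0104). In the fit without it PDK4 was at 0.79 ± 0.13 (SE, n = 3 libraries per group; adjusted p = 0.171), SPRY4 at −0.58 ± 0.13 (0.536) and MSMO1 at −0.26 ± 0.06 (0.536). Cholesterol synthesis genes had a median of −0.13 (0 called of 25, 4 down adjusted over the list alone; adjusted p = 0.198 with an estimated correlation). Immediate early genes were at −0.07 (0 called of 28, 6 down adjusted over the list alone; adjusted p = 0.234 with an estimated correlation). Fatty acid oxidation was at 0.11 (0 called of 25, 1 up adjusted over the list alone; adjusted p = 0.234 with an estimated correlation). Oxidative phosphorylation was at 0.05 (0 of 40 adjusted over the list alone; adjusted p = 0.654 with an estimated correlation). Proliferation was at 0.16 (0 of 29 adjusted over the list alone; adjusted p = 0.509 with an estimated correlation). Without the Published libraries 202 genes were called, 25 above 0 and 177 below. With GC correction in addition there were 75, 24 above 0 and 51 below.

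The Sensitized and Hyper responses, which share no library, shared 6 called genes of the same sign. With GC correction the number was also 6, but without IDI1 and LRRC8B. It was 3 with the replicate block, 63 with no low-count filter, 152 without the Published libraries and 108 with GC correction in addition. Of the uncorrected 6, IDI1, LRRC8B and UCP1 rose and KLHL24 and BTG2, named after its values were seen, fell in both. Independent lists would share 0.0163 rises and 0.174 falls. Of the 179 genes called in either, 173 had the same sign in both, and across all 18519 genes, which are not independent replicates, the fold changes correlated with a Pearson r of 0.151 and a Spearman rho of 0.226. Between Published and Sensitized r was −0.0118 and 29 of 74 called genes had the same sign. Between Published and Hyper r was −0.179 and 10 of 111 had the same sign. The fold changes of all 3 responses followed transcript GC content (Spearman rho 0.328 in Published, −0.155 in Sensitized and −0.422 in Hyper). The sign counts and correlations above are not corrected for it.

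The comparisons with primary adipocytes ask how close each culture came to fat cells from tissue. In the Published culture fat-cell genes were far lower than in Primary. ADIPOQ was at 1256 ± 128 against 12283 ± 5315 CPM (SD, n = 3; log2 −3.29 ± 0.37, SE; adjusted p = 0.000561), CEBPA at −3.00 ± 0.27, PLIN1 at −2.67 ± 0.23, PPARG at −2.35 ± 0.15, LIPE at −2.73 ± 0.26, SLC2A4 at −2.03 ± 0.24 and IRS1 at −1.87 ± 0.10. FABP4 did not differ by the test (−0.10 ± 0.28; adjusted p = 0.795), and LEP was at 0.0999 against 107 ± 119 CPM. Of 24 mature adipocyte markers 19 were lower and 1 higher (21 and 1 adjusted over the list alone; adjusted p = 0.0373 with an estimated correlation), the latter CIDEA, named after its values were seen, at 3.10 ± 0.70. Interferon-response genes were higher in 24 of 25 cases and lower in 0 (25 and 0 adjusted over the list alone; adjusted p = 0.0373 with an estimated correlation), with the antiviral RSAD2 at 202 ± 10.4 against 0.293 ± 0.111 CPM and the RNA sensor RIGI at 4.67 ± 0.15. UCP1 was higher, at 154 ± 3.24 against 3.69 ± 1.33 CPM, though of 17 brown and beige genes 8 were higher and 8 lower (camera adjusted p = 0.457).

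Metabolic lists were lower in Published than in Primary. Of 23 fatty acid synthesis genes 19 were lower and 1 higher (21 and 1 adjusted over the list alone; adjusted p = 0.0972 with an estimated correlation). ACACB was at −3.44 ± 0.21. Fatty acid oxidation genes were lower in 19 of 24 cases and higher in 2, also adjusted over the list alone (adjusted p = 0.0972 with an estimated correlation). Glycolysis genes were lower in 15 of 19 cases and higher in 0, also adjusted over the list alone (adjusted p = 0.156 with an estimated correlation). Cholesterol genes were lower in 16 of 25 cases and higher in 0 (17 and 0 adjusted over the list alone; adjusted p = 0.242 with an estimated correlation). Oxidative phosphorylation genes were lower in 23 of 40 cases and higher in 0 (24 and 0 adjusted over the list alone; adjusted p = 0.360 with an estimated correlation). Insulin signalling genes were lower in 16 of 29 cases and higher in 3, also adjusted over the list alone (adjusted p = 0.0972 with an estimated correlation). FOXO targets were lower in 12 of 22 cases and higher in 2 (13 and 3 adjusted over the list alone; adjusted p = 0.104 with an estimated correlation). Lipid droplet genes were lower in 13 of 20 cases and higher in 2 (15 and 2 adjusted over the list alone; adjusted p = 0.129 with an estimated correlation). Glucocorticoid genes were lower in 12 of 17 cases and higher in 2 (13 and 2 adjusted over the list alone; adjusted p = 0.238 with an estimated correlation). Hypoxia genes were lower in 10 of 21 cases and higher in 2 (11 and 2 adjusted over the list alone; adjusted p = 0.554 with an estimated correlation).

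Lists of other cell types were higher in Published than in Primary. Of 12 skeletal muscle markers 10 were higher and 0 lower (11 and 0 adjusted over the list alone; adjusted p = 0.238 with an estimated correlation), such as the intermediate filament DES at 76.8 ± 11.1 against 0.223 ± 0.109 CPM and cardiac actin ACTC1 at 32.7 ± 20.6 against 0.0551 ± 0.0155 CPM. Proliferation genes were higher in 19 of 29 cases and lower in 0, also adjusted over the list alone (adjusted p = 0.191 with an estimated correlation). MKI67 was at 28.2 ± 2.10 against 1.03 ± 0.572 CPM. Endothelial markers were higher in 7 of 11 cases and lower in 0, also adjusted over the list alone (adjusted p = 0.129 with an estimated correlation). KDR was at 107 ± 6.53 against 1.34 ± 0.936 CPM. Neural markers were higher in 7 of 12 cases and lower in 2 (8 and 2 adjusted over the list alone; adjusted p = 0.129 with an estimated correlation). SNAP25 was at 9.10 ± 0.972 against 0.163 ± 0.101 CPM. Pluripotency markers were higher in 7 of 10 cases and lower in 0, also adjusted over the list alone (adjusted p = 0.129 with an estimated correlation), the levels being low, with DPPA4 at 3.22 ± 0.563 CPM and ZFP42 at 1.23 ± 0.226 CPM in Published. Mesothelial markers were higher in 4 of 7 cases and lower in 2, also adjusted over the list alone (adjusted p = 0.0972 with an estimated correlation), among them KRT8 at 12.3 ± 1.98 CPM and HP, an acute-phase protein, at 249 ± 13.4 CPM. Lymphocyte markers were higher in 4 of 5 cases and lower in 1, also adjusted over the list alone (adjusted p = 0.0972 with an estimated correlation), the clearest being the chemokine CCL5 and the receptor IL7R, at 7.51 ± 0.161 and 8.04 ± 0.834 CPM. Progenitor markers were higher in 10 of 21 cases and lower in 2, also adjusted over the list alone (adjusted p = 0.191 with an estimated correlation). DLK1 was at 31.9 ± 5.23 against 0.188 ± 0.0982 CPM. Matrix genes were higher in 14 of 27 cases and lower in 5 (15 and 5 adjusted over the list alone; adjusted p = 0.432 with an estimated correlation). CCN2 was at 3.27 ± 0.18. Inflammation genes were higher in 17 of 25 cases and lower in 2, also adjusted over the list alone (adjusted p = 0.0972 with an estimated correlation). CCL2 was at 2.54 ± 0.18. Of 16333 genes edgeR called 7428, with 3890 higher and 3538 lower in Published, and 4780 differed at least 2-fold.

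Other genes near 0 in Primary were the retinoid carrier CRABP1 at 22.1 ± 4.71 against 0.0324 CPM, LGI1 at 53.1 ± 4.54 against 0.0916 CPM and CYTL1 at 26.8 ± 3.26 against 0.0441 CPM, and the fetal growth factor IGF2 was at 570 ± 221 against 1.58 ± 0.552 CPM. Near 0 in Published were the methyltransferase BHMT2 at 0.0124 against 37.0 ± 23.1 CPM, the cytochrome oxidase subunit COX7A1 at 0.0321 against 32.7 ± 16.1 CPM, TMEM176B at 0.139 against 35.8 ± 30.1 CPM, ADIRF at 0.836 against 203 ± 80.9 CPM and the imprinted RNA MEG3 at 0.129 against 28.0 ± 19.98 CPM.

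In the Sensitized culture fat-cell genes were lower than in Primary as well. ADIPOQ was at 715 ± 42.9 against 13367 ± 5852 CPM (SD, n = 3; log2 −4.23 ± 0.38, SE), LIPE at −3.18 ± 0.17, PLIN1 at −1.83 ± 0.19, FABP4 at −1.74 ± 0.21, CEBPA at −1.68 ± 0.14, PPARG at −1.51 ± 0.14, SLC2A4 at −1.23 ± 0.20 and INSR at −0.59 ± 0.13 (edgeR adjusted p = 0.0106). PDK4 was at −4.73 ± 0.40, and UCP1 was higher, at 1.73 ± 0.26. Of 24 mature adipocyte markers 20 were lower and 1 higher, also adjusted over the list alone (adjusted p = 0.0999 with an estimated correlation). Glucocorticoid genes were lower in 14 of 17 cases and higher in 1, also adjusted over the list alone (adjusted p = 0.128 with an estimated correlation). ZBTB16 was at 9.03 ± 0.572 against 214 ± 69.7 CPM. Interferon genes were higher in 23 of 25 cases and lower in 0, also adjusted over the list alone (adjusted p = 0.129 with an estimated correlation). RIGI was at 3.12 ± 0.11 and IFI6 at 1045 ± 135 against 67.2 ± 2.78 CPM. ATF4 targets were higher in 12 of 28 cases and lower in 4, also adjusted over the list alone (adjusted p = 0.590 with an estimated correlation). SLC7A11 was at 2.93 ± 0.11.

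No list kept its call with an estimated correlation in this comparison. Oxidative phosphorylation genes were lower in 33 of 40 cases and higher in 0 (34 and 0 adjusted over the list alone; adjusted p = 0.238 with an estimated correlation). Fatty acid oxidation genes were lower in 20 of 24 cases and higher in 0 (21 and 0 adjusted over the list alone; adjusted p = 0.128 with an estimated correlation). Fatty acid synthesis genes were lower in 19 of 23 cases and higher in 1, also adjusted over the list alone (adjusted p = 0.128 with an estimated correlation). ACACB was at −4.24 ± 0.17. Cholesterol synthesis genes were lower in 20 of 25 cases and higher in 0 (24 and 0 adjusted over the list alone; adjusted p = 0.149 with an estimated correlation). Glycolysis genes were lower in 14 of 19 cases and higher in 3, also adjusted over the list alone (adjusted p = 0.194 with an estimated correlation). HK2 was at −3.18 ± 0.18. Lipid droplet genes were lower in 13 of 20 cases and higher in 2, also adjusted over the list alone (adjusted p = 0.128 with an estimated correlation). FOXO targets were lower in 13 of 23 cases and higher in 3, also adjusted over the list alone (adjusted p = 0.128 with an estimated correlation). Insulin signalling genes were lower in 16 of 29 cases and higher in 3, also adjusted over the list alone (adjusted p = 0.129 with an estimated correlation). IRS2 was at −1.66 ± 0.09. Ribosome biogenesis genes were lower in 16 of 30 cases and higher in 2 (17 and 2 adjusted over the list alone; adjusted p = 0.475 with an estimated correlation). Heat shock genes were lower in 7 of 18 cases and higher in 0 (5 and 0 adjusted over the list alone; adjusted p = 0.582 with an estimated correlation). Higher in Sensitized were skeletal muscle markers in 9 of 11 cases, also adjusted over the list alone (adjusted p = 0.186 with an estimated correlation). DES was at 45.6 ± 9.49 CPM. Proliferation genes were higher in 18 of 29 cases (19 up and 1 down adjusted over the list alone; adjusted p = 0.218 with an estimated correlation). Endothelial markers were higher in 8 of 12 cases, also adjusted over the list alone (adjusted p = 0.128 with an estimated correlation). Mesothelial markers were higher in 4 of 7 cases with 1 lower, also adjusted over the list alone (adjusted p = 0.129 with an estimated correlation). KRT8 was at 41.1 ± 5.30 against 0.222 CPM. Neural markers were higher in 7 of 12 cases with 1 lower (8 and 1 adjusted over the list alone; adjusted p = 0.128 with an estimated correlation). Pluripotency markers were higher in 8 of 10 cases with 1 lower, also adjusted over the list alone (adjusted p = 0.129 with an estimated correlation). Lymphocyte markers were higher in 3 of 4 cases (3 up and 1 down adjusted over the list alone; adjusted p = 0.186 with an estimated correlation).

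Near 0 in Primary were CYTL1 at 29.1 ± 1.07 against 0.0478 CPM, FRRS1L at 20.1 ± 0.711 against 0.0378 CPM, the tight junction protein CLDN1 at 54.5 ± 2.59 against 0.108 CPM, LGI1 at 33.7 ± 2.64 against 0.0998 CPM, DLK1 at 66.3 ± 6.30 against 0.205 CPM and TMEM130 at 40.1 ± 1.21 against 0.147 CPM. Near 0 in Sensitized were COX7A1 at 0.0251 against 35.4 ± 17.2 CPM, BHMT2 at 0.1004 against 40.2 ± 25.2 CPM, the cannabinoid receptor CNR1 at 0.401 against 133 ± 138 CPM, LEP at 0.478 against 116 ± 130 CPM, TMEM176A at 0.0965 against 21.1 ± 18.4 CPM and CYP4B1 at 0.149 against 29.3 ± 35.4 CPM. Of 17147 genes edgeR called 8845, with 4640 higher and 4205 lower in Sensitized, and 5152 differed at least 2-fold.

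In the Hyper culture the same panel was lower than in Primary. ADIPOQ was at 576 ± 9.34 against 13344 ± 5838 CPM (SD, n = 3; log2 −4.53 ± 0.37, SE), LIPE at −3.36 ± 0.18, PLIN1 at −1.94 ± 0.19, FABP4 at −1.81 ± 0.20, CEBPA at −1.78 ± 0.14, PPARG at −1.45 ± 0.14, SLC2A4 at −1.35 ± 0.20 and INSR at −0.73 ± 0.14 (edgeR adjusted p = 0.00526). FKBP5 was at 49.7 ± 2.20 against 1313 ± 381 CPM, and UCP1 was higher, at 1.60 ± 0.27. Of 24 mature adipocyte markers 20 were lower and 1 higher, also adjusted over the list alone (adjusted p = 0.0728 with an estimated correlation), and of 25 interferon genes 23 were higher and 0 lower, also adjusted over the list alone (adjusted p = 0.0728 with an estimated correlation). RIGI was at 3.12 ± 0.08 and IFI6 at 4.03 ± 0.11. Glucocorticoid genes were lower in 14 of 17 cases and higher in 1, also adjusted over the list alone (adjusted p = 0.0889 with an estimated correlation).

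No list kept its call with an estimated correlation here either. Oxidative phosphorylation genes were lower in 33 of 40 cases and higher in 0, also adjusted over the list alone (adjusted p = 0.285 with an estimated correlation). Fatty acid oxidation genes were lower in 20 of 24 cases and higher in 0, also adjusted over the list alone (adjusted p = 0.0728 with an estimated correlation). Fatty acid synthesis genes were lower in 19 of 23 cases and higher in 1, also adjusted over the list alone (adjusted p = 0.0728 with an estimated correlation). ACACB was at −4.40 ± 0.17. Cholesterol synthesis genes were lower in 20 of 25 cases and higher in 0 (23 and 0 adjusted over the list alone; adjusted p = 0.164 with an estimated correlation). Glycolysis genes were lower in 12 of 19 cases and higher in 3 (13 and 3 adjusted over the list alone; adjusted p = 0.156 with an estimated correlation). Lipid droplet genes were lower in 13 of 20 cases and higher in 2 (14 and 2 adjusted over the list alone; adjusted p = 0.0891 with an estimated correlation). FOXO targets were lower in 13 of 23 cases and higher in 3, also adjusted over the list alone (adjusted p = 0.0889 with an estimated correlation). Insulin signalling genes were lower in 15 of 29 cases and higher in 3 (16 and 3 adjusted over the list alone; adjusted p = 0.118 with an estimated correlation). IRS1 was at −1.42 ± 0.08. Ribosome biogenesis genes were lower in 16 of 30 cases and higher in 2, also adjusted over the list alone (adjusted p = 0.494 with an estimated correlation). Heat shock genes were lower in 6 of 18 cases and higher in 0, also adjusted over the list alone (adjusted p = 0.606 with an estimated correlation). Higher in Hyper were skeletal muscle markers in 10 of 12 cases, also adjusted over the list alone (adjusted p = 0.128 with an estimated correlation). DES was at 51.8 ± 11.3 CPM. Proliferation genes were higher in 19 of 29 cases (19 up and 1 down adjusted over the list alone; adjusted p = 0.232 with an estimated correlation). Progenitor markers were higher in 9 of 21 cases with 3 lower, also adjusted over the list alone (adjusted p = 0.336 with an estimated correlation). PRRX1 was at 1.40 ± 0.13. ATF4 targets were higher in 12 of 28 cases with 4 lower, also adjusted over the list alone (adjusted p = 0.606 with an estimated correlation). Endothelial markers were higher in 9 of 13 cases with 1 lower, also adjusted over the list alone (adjusted p = 0.0891 with an estimated correlation). Mesothelial markers were higher in 4 of 7 cases with 1 lower, also adjusted over the list alone (adjusted p = 0.0728 with an estimated correlation). KRT18 was at 52.5 ± 5.01 against 0.238 CPM. Neural markers were higher in 7 of 12 cases with 1 lower, also adjusted over the list alone (adjusted p = 0.0728 with an estimated correlation). Pluripotency markers were higher in 8 of 10 cases with 1 lower (9 and 1 adjusted over the list alone; adjusted p = 0.118 with an estimated correlation). Lymphocyte markers were higher in 3 of 4 cases with 1 lower, also adjusted over the list alone (adjusted p = 0.140 with an estimated correlation).

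The largest differences from Primary in the Hyper culture were CYTL1 at 28.6 ± 0.429 against 0.0477 CPM, CLDN1 at 54.6 ± 2.15 against 0.108 CPM, DLK1 at 64.3 ± 2.90 against 0.205 CPM, ANGPTL7 at 49.4 ± 1.48 against 0.156 CPM, LGI1 at 30.5 ± 0.871 against 0.0996 CPM and TMEM130 at 37.9 ± 2.19 against 0.147 CPM. In the other direction were LEP at 0.106 against 116 ± 130 CPM, MEG3 at 0.0472 against 30.4 ± 21.8 CPM, BHMT2 at 0.0621 against 40.1 ± 25.1 CPM, CNR1 at 0.286 against 132 ± 137 CPM, COX7A1 at 0.0915 against 35.4 ± 17.2 CPM and TMEM176A at 0.0541 against 21.1 ± 18.4 CPM. Of 17072 genes edgeR called 8775, with 4599 higher and 4176 lower in Hyper, and 5139 differed at least 2-fold.

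The last comparison asks which culture came closest to primary adipocytes across all genes. Across 18118 genes, the Spearman correlation with the mean of Primary was 0.898 ± 0.00472 (SD, n = 3) for Published, 0.902 ± 0.00112 for Sensitized and 0.900 ± 0.000620 for Hyper. Exact two-sided permutation tests gave p = 0.4 for Sensitized against Published, 0.7 for Hyper against Published and 0.3 for Hyper against Sensitized, where the smallest p that 3 against 3 libraries allow is 0.1, so no difference could pass 0.05 whatever the data. Without Published replicate 1, Sensitized minus Published went from 0.00327 to 0.000436 and Hyper minus Published from 0.00225 to −0.000532. Each Primary library correlated with the mean of the other 2 at 0.975 to 0.983.

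On GRCh38, PDK4 (ENSG00000004799) lies on the minus strand of chromosome 7 from 95583499 to 95596491. KLHL24 (ENSG00000114796) spans 183635568 to 183684477 and ADIPOQ (ENSG00000181092) 186842690 to 186858463, both on the plus strand of chromosome 3. UCP1 (ENSG00000109424) lies on the minus strand of chromosome 4 from 140559434 to 140568805, FKBP5 (ENSG00000096060) on the minus strand of chromosome 6 from 35573585 to 35728583, and SAA1 (ENSG00000173432) on the plus strand of chromosome 11 from 18266174 to 18269977. JUNB (ENSG00000171223) lies on the plus strand of chromosome 19 from 12791496 to 12793315 and RSAD2 (ENSG00000134321) on the plus strand of chromosome 2 from 6865806 to 6898239. The values reported are for whole genes, so no exon or untranslated region is singled out.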

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

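The tests chosen after the data were seen are the GC correction, the omission of the Published libraries, both together, the regroupings of libraries, the median of all genes, the share of members past the test of the difference, and the use of the omission of Published replicate 1. The difference between the Sensitized and Published insulin responses passed its own test for 27 genes and is singled out for that reason. The difference was below 0 for FOXO targets that insulin lowers, with a list median of −0.19: PDK4 at −1.10, PIK3IP1 at −1.05 and KLHL24 at −0.76, and outside the list COQ8A at −0.72 and HBP1 at −0.51. Cholesterol genes lay above 0, with HMGCS1 at 0.59 and MSMO1 at 0.39, though 4 of 25 in that list passed, its adjusted p was 0.153 with an estimated correlation, and MSMO1 lost its call with GC correction (0.31; adjusted p = 0.0539). Also above 0 were PIK3R1 at 0.58, NFIL3 at 0.60, SYN2 at 0.96, LRRC8B at 0.57 and the chaperones HSPA8 at 0.53 and HSPH1 at 0.39. The libraries were regrouped in 100 ways that keep 3 in each group, drawn with a fixed seed from all such ways and including the real one. Of these 10 called at least as many genes as the real grouping, and the highest other count was 1302. Of those ways 13 part Published replicates 1 and 2 and Published replicate 2 with insulin from the other Published libraries, and 7 of these reached 27, while 2 further ways did, the higher with 41. Both of these keep the Sensitized libraries with and without insulin apart, as 13 of the 100 ways do, each with at least 12 genes, so they hold the real Sensitized response. The 76 ways that mix these libraries and do not follow that parting of Published called at most 2. By the count over all 100 ways, chance cannot be excluded for the number of genes called.

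In the Published insulin response edgeR called 0 genes, while DESeq2 called 31 and edgeR with no low-count filter 934. With GC correction 1 gene was called and without Published replicate 1 there were 0. This argues against a GC trend and against that library alone as the cause. Without Published replicate 3 there were 2972, so the count of 0 depends on which libraries are kept. That omission leaves Published replicates 1 and 2, with mitochondrial shares of 19.03% and 11.98% and GC trends of −0.69 and −0.31. The 2972 calls may therefore reflect these libraries rather than insulin. Spread alone would hide changes of the same size. Of the cholesterol and FOXO genes called in Sensitized, 70.0% (7 of 10) passed the test of the difference. They were chosen for a response that this difference contains, so their share is raised and cannot decide about spread. A real count of 0 is reached by all 10 regroupings whatever the data, but the highest, 2578 genes, set Published replicates 1 and 2 and Published replicate 2 with insulin against the rest, which points to a structure of the samples. If the medium of this culture already held much insulin, its cells could answer less to more of it, and no measurement here tests that.

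The 104 falls in the Hyper insulin response had a median log2 change of −0.61 (SD over genes 0.38, median SE 0.119), which became −0.31 (SD 0.34) with GC correction, with 101 still negative. Of the falls 21.2% (22) were still called with GC correction, as a GC trend between libraries would give. With GC correction and without the Published libraries 64.4% (67) were called. Leaving out those libraries alone raised the calls from 111 to 1644 and kept all 111, so the shares with and without them are not on one footing. The trend as fitted does not account for the 67 genes, but a remainder that the correction missed is not excluded. The median of all genes, −0.00118, is held near 0 by the scaling and decides nothing about a few genes taking most of the counts. In Sensitized with GC correction 76.9% (80) were negative against 50.8% of all genes, as acute insulin would give. A remainder of the GC trend could give this too. The falls had a median GC content of 64.3%, and the uncorrected Sensitized response followed GC content in the same direction (Spearman rho −0.155). Genes of like GC content were not compared, so this share cannot tell insulin from the trend. A GC trend may therefore account for part of the size of the falls, and acute insulin remains open as the cause for the 67 genes.

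Without the Published libraries, 202 genes differed between the Hyper and Sensitized insulin responses, and 30.2% (61) were still called with GC correction. The median of those below 0 went from −0.53 (SD over genes 0.31) to −0.33 (SD 0.31). The GC trend was lower with acute insulin in Hyper, so a trend and a difference between the responses could give the same genes, and these values cannot tell which.

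Regrouping the libraries gave these counts for the other comparisons. In the Sensitized insulin response 1 of 10 ways, the real one, called as many as 74 genes and the highest other count was 0. In the Hyper insulin response it was 1 of 10 for 111 genes, with 0 the highest other. For the difference between Hyper and Sensitized responses 100 ways were drawn with a fixed seed, and all 100 reach the real count of 0 whatever the data, so they decide nothing, and the highest other count was 19. For Sensitized against Published cultures it was 1 of 10 for 9288 genes, and for Hyper against Sensitized cultures 1 of 10 for 3 genes, each with 0 the highest other. For Published, Sensitized and Hyper against Primary it was 1 of 10 each, for 7428, 8845 and 8775 genes, with 0 the highest other. Where only 10 ways exist, they are too few for a share under 0.05.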

How the results depend on the processing

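Chosen after the results were seen were GC correction, omission of the Published libraries, and omission of Published replicate 1 where Published is not compared. Combinations with GC correction were too. Leaving out Published replicate 1 was planned for the other results. Replicate numbers did not pair libraries across groups: expression residuals of equal numbers correlated with a median r of −0.000344 against −0.00423 for unequal ones, so the block is given only as an alternative. The counts of the insulin responses depend on which Published libraries are kept. In the culture comparison with Published, the number of genes called changed by at most 1.5-fold under every setting except the 2-fold minimum. This holds for the number and not for which genes are called. RLE size factors gave 4431 rises and 4859 falls against 4777 and 4511, and GC correction did not keep all of the calls, as given above.

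With a minimum change of 2-fold, edgeR called 6 genes in the Sensitized insulin response, 15 in Hyper, 4 in the difference between Sensitized and Published, 1988 and 0 in the culture comparisons with Published and with Hyper, and 4780, 5152 and 5139 against Primary for Published, Sensitized and Hyper. With no low-count filter it called 934 in the Published response, 178 in Sensitized, 858 in Hyper, 745 and 171 in the differences Sensitized minus Published and Hyper minus Sensitized, 22 between Hyper and Sensitized cultures and 63 shared genes, and the difference in similarity to Primary between Hyper and Sensitized was −0.00248. DESeq2 called 31, 199 and 409 in the Published, Sensitized and Hyper responses, 157 and 2 in the differences, and 9 between Hyper and Sensitized cultures. With the replicate number as a block 49 genes were called in Hyper and 3 shared.

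With only the libraries compared, 532 genes were called in the Sensitized response, 1249 in Hyper, 14 and 202 in the differences, and 44 between Hyper and Sensitized cultures. With GC correction the counts were 1 for Published, 158 for Sensitized, 37 (8 up and 29 down) for Hyper, 65 and 1 for the differences, and 5 between Hyper and Sensitized cultures. Without the Published libraries they were 404 for Sensitized, 1644 (553 up and 1091 down) for Hyper, 202 for the difference Hyper minus Sensitized, 19 between these cultures and 152 shared. With GC correction and without the Published libraries they were 519, 593 (266 up and 327 down), 75, 29 and 108 in the same order. With GC correction and without Published replicate 1 the difference Sensitized minus Published had 64.

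Leaving out single libraries, the Published response ranged from 0 to 2972 genes: 2972 without Published replicate 3 and 1 without Published replicate 2 or Published replicate 1 with insulin. Its skeletal muscle list ranged from a median of −0.85 without Published replicate 1 to 0.0743, turned, without Published replicate 2. The Sensitized response ranged from 31 to 211: 36, 31 and 47 without Sensitized replicates 1, 2 and 3, 35 and 38 without replicates 1 and 3 with insulin, and 211 without Published replicate 1. The Hyper response ranged from 0 to 841: 4, 0 and 0 without Hyper replicates 1, 2 and 3, 107, 2 and 2 without those with insulin, and 841 without Published replicate 1. The difference Sensitized minus Published ranged from 12 to 2038: 2038 without Published replicate 3, 42 without Published replicate 1, 17 without Sensitized replicate 2 and 12 without Sensitized replicate 3 with insulin. The difference Hyper minus Sensitized ranged from 0 to 1, with 1 without Hyper replicate 1 with insulin or Published replicate 1. The cultures ranged from 8194 to 9879 for Sensitized minus Published and from 0 to 6 for Hyper minus Sensitized: 0 without Sensitized replicate 1 or 2 or Hyper replicate 3, 1 without Hyper replicate 1 or 2, and 6 without Published replicate 1. Against Primary the ranges were 5091 to 7801 for Published, 6456 to 10092 for Sensitized and 6333 to 9913 for Hyper. Differences in similarity to Primary ranged from −0.000532 (without Published replicate 1) to 0.00385 for Hyper minus Published, −0.00159 to −0.000639 for Hyper minus Sensitized and 0.000436 (without Published replicate 1) to 0.00481 for Sensitized minus Published. Over all comparisons 14 list calls were kept and 116 lost with an estimated correlation, and fry kept 95 and lost 35.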

Other observations

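The tests and genes of this part were all chosen after the values were seen. Primary adipocytes expressed HOX genes, which mark position along the body axis, that stem-cell-derived adipocytes expressed little. HOXC8 was at 31.3 CPM in Primary and 0.686, 0.660 and 0.591 CPM in Published, Sensitized and Hyper, HOXC6 at 33.2 against 0.889, 0.659 and 0.748 CPM, and HOXC10 at 42.1 against 2.76, 3.35 and 2.73 CPM. Of 29, 29 and 28 HOX genes tested, 26, 26 and 25 were lower and 2, 2 and 1 higher than in Primary, with camera p = 0.00573, 0.00920 and 0.00506 with an estimated correlation (limma, not adjusted). HOXA13, the most distal gene of its cluster, went the other way, at 0.607 CPM in Primary against 3.27, 3.53 and 3.45 CPM. Other position and lineage factors differed too: PAX3 was at 0.555 against 25.6, 26.7 and 26.3 CPM, LHX8 at 0.0282 against 8.59, 10.3 and 10.5 CPM, TBX15 at 76.2 against 19.3, 18.2 and 17.4 CPM, and SIM1 at 34.4 against 3.13, 1.69 and 1.42 CPM.

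Several imprinted genes, expressed from 1 parental copy, differed in both directions and were not tested as a group. MEG3 was at 31.0 ± 21.9 CPM in Primary (SD, n = 3) against 0.141, 0.192 and 0.0488 CPM in Published, Sensitized and Hyper, and PEG3 at 16.7 against 0.298, 0.360 and 0.228 CPM. DLK1, which lies beside MEG3, was at 0.208 against 35.0, 68.5 and 66.5 CPM, IGF2 at 1.76 against 625, 372 and 348 CPM, and H19 at 232 ± 261 against 4375, 2673 and 2509 CPM. COX7A1, a muscle and fat form of a cytochrome oxidase subunit, was at 36.1 against 0.0354, 0.0259 and 0.0946 CPM.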
